A study of Mus musculus with 2 samples.

How the data were processed

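Whole-genome bisulfite libraries were prepared by adaptor tagging after bisulfite treatment from 2 pools of post-replicative mouse zygotes, 1 control and 1 TET3 deletion pool. Zygotes were collected 24 to 25 hours after human chorionic gonadotrophin, per the labels. Groups were taken from the genotype in the labels, with 1 library per group. The submitters' processing notes name Trim Galore 0.3.5, Bismark 0.10.0 and the genome build NCBIM37. Trimming settings, removal of duplicate reads and alignment settings are not given in the sources used here. If duplicate reads were kept, counts at a position overstate the number of molecules.

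The deposited counts are methylated and unmethylated calls at each CpG cytosine, with each strand on a line of its own and positions without calls not listed. The deposited percent is the share of methylated calls among all calls at that position, and it matched the counts at every position to within 3.8e-06. No position was listed more than once. Calls per library, and the median and spread of calls per position, were computed from the counts: 31.8% of listed autosomal positions in the control and 41.1% in the deletion library had at least 5 calls, and 0.546% and 1.27% had over 20. The deletion library held 1.34 times the autosomal calls of the control. Of 35212687 autosomal positions listed in either library, the control listed 82.8% and the deletion library 90.3%.

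Levels were computed by pooling calls, as methylated calls over all calls, with exact binomial (Clopper-Pearson) intervals at 95%. The difference is deletion minus control in percentage points. With 1 library per genotype no p-value for the genotype can be had, and the SD over 19 autosomes and the jackknife over 500 kb blocks describe variation along the genome. The strand of a position was inferred from runs of adjacent positions, which gave a strand to 88.5% of autosomal positions. CpG density was the number of CpGs in the surrounding 500 bp, from positions listed in either library, so it is too low where neither library had calls. Windows of 5 kb were put in level classes by the mean of both libraries on the top strand, with at least 25 calls per strand and library, and measured on the bottom strand, so that the same calls did not both class and measure a window. The floxed exon was located by matching the CpG spacing of the exon sequence in the labels to the listed positions, since no genome of the files' build was used here. It was compared with autosomal stretches of the same length whose number of listed positions was within 4 and whose total of calls was within 25% of its own, and its methylation with those of them that had at least 30 calls per library and a level within 10 points.

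Windows of 5 kb with at least 50 calls in each library were tested with Fisher's exact test (two-sided) on methylated and unmethylated calls, with Benjamini-Hochberg adjustment over all windows tested. A window was called at an adjusted p under 0.05 and a difference of at least 10 percentage points. The same test between the top and bottom strand of 1 library gave the rate of calls without a difference in genotype or library. Because that rate was high, a chi-square test divided by the dispersion between strands (3.61 in the control and 3.75 in the deletion library at 5 kb, the larger used) was added after the data were seen, at window sizes of 5, 20, 100 and 500 kb, with at least 25 calls per strand and library at 5 and 20 kb, 125 at 100 kb and 625 at 500 kb. The named windows were the 5 with the largest rise and the 5 with the largest fall among called windows with the same sign on both strands and at least 10 calls per strand and library.

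The tests were checked on simulated calls at the depths of the 458282 windows. With independent calls, Fisher's exact test recovered 51.5% of 200 windows changed by 20 points and 96% of 200 changed by 40 points, with 18 false calls among 457882 unchanged windows. With calls correlated at a dispersion of 4, it called 14.6% of the unchanged windows. A chi-square test divided by the dispersion used in the simulation then called 2 unchanged windows and recovered 11.5% and 55% of the changed windows. Strands were not simulated in these windows, so the estimate of the dispersion from strands was not checked. Strand inference was right for 99.97% of positions when 93% of positions were kept.

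The tests, classes, thresholds, rule for named windows and most alternatives were fixed before the data were examined. Alternatives were at least 5 calls per position, leaving out positions over 20 calls, positions listed in both libraries, equal weight per position and each strand alone. For windows they were at least 100 calls, a difference of 20 points, 1 position per 100 bp, calls thinned to the shallower library, the genome-wide difference taken off, the same sign on both strands, and windows of 2 and 10 kb. For the exon, calls on the same chromosome or in the same density class served as the denominator. Added after the data were seen were the strand-scaled test at 5 and 500 kb, the split of CpGs by recurring spacing, the jackknife, the comparison of the Tet3 exon with similar stretches, and the analysis of CpG-dense clusters. Promoters, gene bodies, exons and introns as classes, and lists of genes had been planned and are not analysed here, since they need an annotation of the NCBIM37 build and the table of genes used here is on another build. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.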

Results

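CpG methylation was measured by whole-genome bisulfite sequencing in pooled mouse zygotes collected after DNA replication, 12 to 13 hours after insemination. TET3 is the dioxygenase that oxidises 5-methylcytosine in the fertilised egg, and bisulfite sequencing reads both 5-methylcytosine and 5-hydroxymethylcytosine as methylated. The control pool held 225 zygotes of females with floxed Tet3 alleles and no Cre, and 120 of these had 129S2/SvHsd fathers. The TET3 deletion pool held 237 zygotes of floxed females carrying Zp3-Cre, which is active in growing oocytes, and 129 of these had 129S2/SvHsd fathers. The other fathers were of C57BL/6J background. Each pool combined 3 collections and gave 1 library, so no value below has a replicate spread, and each test on calls compares the 2 libraries, not the genotypes. The control library held 125415054 calls over 30299024 CpG cytosine positions and the deletion library 166805465 calls over 33035689 positions. A listed autosomal position had a median of 3 calls in the control and 4 in the deletion library. Intervals are exact binomial (Clopper-Pearson) at 95% unless another kind is named, and they cover counting error only, since calls from 1 read or from its PCR copies are not independent.

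The floxed exon of Tet3 was examined first, because the design removes it from the maternal alleles of the deletion pool. It encodes residues that bind the catalytic iron, per the labels. The deletion library held fewer calls on this exon than the control library, and the calls it held were less methylated. The exon spans 151 bp on the minus strand of chromosome 6, from 83325744 to 83325894 in the NCBIM37 build, and was placed by the spacing of its CpGs. All 20 of its CpG positions were listed, with 0 further positions in between, while the next best site in the genome matched 13. The control library had 79 calls there, or 0.630 per 1000000 calls (0.499 to 0.785), and the deletion library 66, or 0.396 per 1000000 (0.306 to 0.503). The ratio of deletion to control was 0.628 (95% interval 0.446 to 0.882, two-sided Fisher's exact test p = 0.00552). The paternal alleles keep the exon by design, so only a partial fall could be seen. Coverage also varied widely elsewhere, so the exon did not stand apart. Of 25842 autosomal stretches of like length, positions and calls, 15.0% had a ratio as low, and the central 95% ran from 0.400 to 2.90. A partial fall lies within that range, so the comparison could neither show nor exclude the deletion. In the adjoining 250 bp, from 83325494 to 83325743, the control held 93 calls and the deletion library 50, a ratio of 0.404. How far the floxed segment extends past the exon was not examined, so this bin may not stand for untouched sequence. Bins starting at 83327494 and 83328494 had ratios of 0.501 and 0.553. On the exon, 89.9% of control calls were methylated (81.0 to 95.5%) against 69.7% of deletion calls (57.1 to 80.4%; two-sided Fisher's exact test p = 0.00287), and 3.96% of 4751 like stretches of similar level fell by as much. The comparison with like stretches was added after the data were seen.

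**Figure D1:**
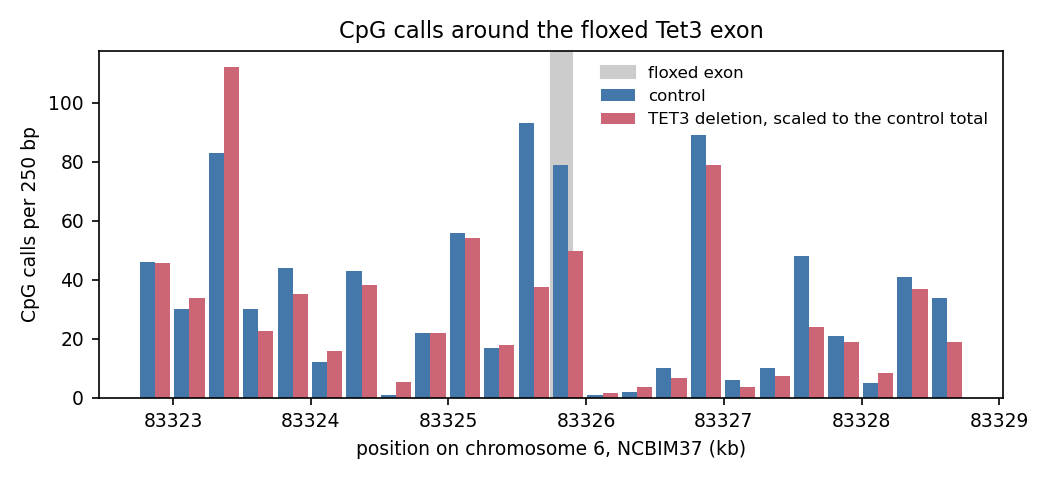
Number of CpG calls per 250 bp (y axis) along chromosome 6 around the floxed Tet3 exon (x axis, kb in the NCBIM37 build; grey band, exon), with bars for the control library and for the deletion library scaled to the control total. Over the exon itself the deletion library held 66 calls against 79 in the control before scaling, a ratio of 0.628 per call sequenced.

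The second comparison asked how much methylation the zygotic genome carried with and without maternal TET3. Autosomal CpGs were more methylated in the deletion library. Of 119966116 autosomal calls in the control, 44.1% were methylated, and of 160182746 in the deletion library, 46.8%, a rise of 2.68 percentage points. Every one of the 19 autosomes was higher in the deletion library, from 1.93 points on chromosome 3 to 3.32 on chromosome 11, with an SD of 0.374 points between autosomes. A jackknife over 4819 blocks of 500 kb gave a standard error of 0.0354 points, which describes the spread along these genomes and not between pools.

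The sex chromosomes went different ways. The X, which is mostly maternal in a pool of both sexes, had 48.8% methylation in the control and 48.5% in the deletion library, a difference of -0.317 points (jackknife interval over 328 blocks, -0.524 to -0.110), and of -0.108 points where both libraries had at least 5 calls. On the top and bottom strand alone the X differed by -0.191 and -0.172 points. Both values leave out positions whose strand could not be inferred, so they do not average to the whole. The Y, which is paternal only, rose from 48.8% to 53.2%, or by 4.43 points. The Y value rested on 15087 positions with 30482 control and 35993 deletion calls, and its jackknife interval over 6 blocks ran from 1.74 to 7.13 points. Mitochondrial DNA, which served as a background of little methylation, read 2.03% and 2.23% methylated, a difference of 0.205 points. The sign of the mitochondrial difference turned to -0.170 points when positions were weighted equally.

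**Figure D2:**
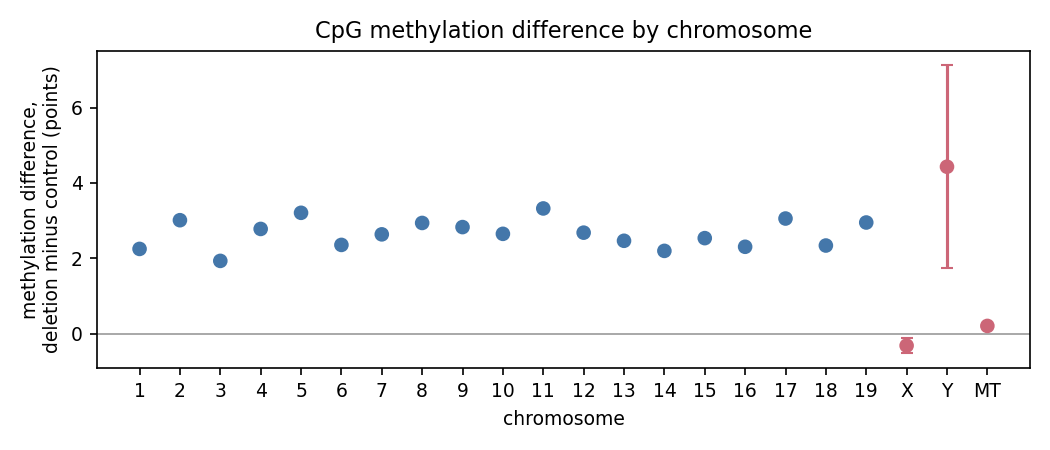
Methylation difference, deletion minus control, in percentage points (y axis) for each chromosome (x axis); points are pooled calls of the 2 libraries, and bars on X and Y are jackknife intervals over 500 kb blocks. All 19 autosomes lie between 1.93 and 3.32 points, X at -0.317, Y at 4.43 and mitochondrial DNA at 0.205.

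CpG density separated the autosomal sequence into parts that rose by different amounts. Pooled over methylation levels, sequence of intermediate density rose most and CpG-dense sequence, which includes CpG islands, rose least in percentage points. Positions with 6 to 10 CpGs in the surrounding 500 bp went from 50.2% to 53.8%, a rise of 3.56 points (SD 0.358 over 19 autosomes). Those with 11 to 20 CpGs rose by 3.44 points (SD 0.602), from 45.6% to 49.1%. The sparsest class, 1 to 5 CpGs, rose by 1.76 points (SD 0.402), from 51.3% to 53.1%. Positions with 21 to 30 CpGs went from 33.6% to 34.3%, a rise of 0.693 points (SD 0.390), and those with over 30 CpGs from 7.51% to 8.01%, a rise of 0.503 points (SD 0.211). With equal weight per position the class of 21 to 30 CpGs rose by 1.48 points, more than the 1.26 points of the sparsest class, and with at least 5 calls per position by 1.07 points. In each of these 5 classes the deletion library was higher on 19 of 19 autosomes. On the X the same 5 classes differed by -0.634, -0.0882, -0.0403, -0.0139 and -1.63 points from the sparsest to the densest, and the densest went from 23.9% to 22.3%. Which autosomal density class rose least depended on the methylation level of the 5 kb window. In windows under 20%, positions with 11 to 20 CpGs rose by 0.167 points and those with over 30 by 0.527. In windows of 20 to 40%, positions with 21 to 30 CpGs differed by -0.638 points and those with over 30 by 0.828. In windows of 40% and over, the densest class rose least.

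The rise also depended on how methylated a region was. Windows of 5 kb were classed by their level on the top DNA strand and measured on the bottom strand, whose reads come from other molecules. Highly methylated windows rose by over 5 points, and lowly methylated windows by about 1 point. The 78174 autosomal windows of 60 to 80% went from 70.3% to 75.7%, a rise of 5.36 points (SD 0.343 over 19 autosomes), and the 64805 windows of 80 to 100% from 79.6% to 84.6%, a rise of 5.04 points (SD 0.291). The 79475 windows of 40 to 60% rose by 2.00 points (SD 0.497), from 46.2% to 48.2%. The largest class, 136322 windows of 20 to 40%, rose by 1.79 points (SD 0.483), from 30.3% to 32.1%. The 32736 windows under 20% rose by 0.992 points (SD 0.222), from 9.67% to 10.7%. Each class was higher on 19 of 19 autosomes. In X windows the differences, deletion minus control, were -1.63, -1.48, -0.603, 1.63 and 3.05 points from the lowest class to the highest.

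**Figure D3:**
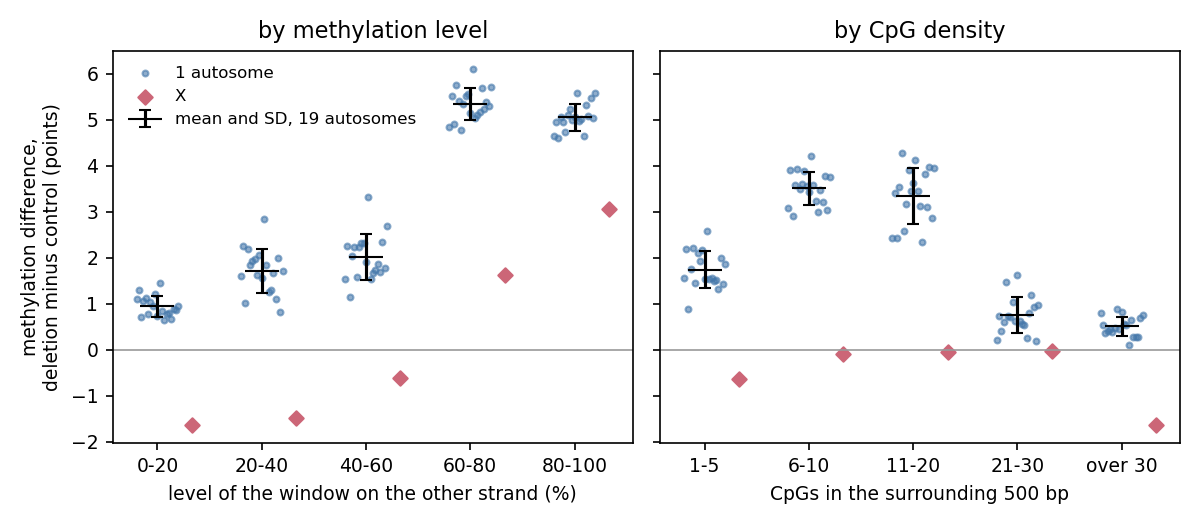
Methylation difference, deletion minus control, in percentage points (y axes), by methylation level of 5 kb windows on the other strand (left x axis, %) and by CpGs in the surrounding 500 bp (right x axis); each circle is 1 autosome, black lines are the mean and SD over 19 autosomes, and diamonds are the X. Pooled over autosomes the rise reaches 5.36 points in windows of 60 to 80% and 3.56 points at 6 to 10 CpGs, and the X lies below the autosomes in every class.

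The distribution of autosomal 5 kb windows had a broad group at low to intermediate level and a second group at high level in both libraries, and the second group lay higher in the deletion library. Among 435018 windows with at least 50 calls in each library, 11.9% of windows had a level of 80 to 100% in the control and 20.2% in the deletion library. Windows of 60 to 80% made up 22.6% in the control and 16.02% in the deletion library. The share at 20 to 40% was 34.8% and 36.0%, at 40 to 60% 22.9% and 20.6%, and under 20% 7.76% and 7.15%. The median difference was 2.03 points, with quartiles of -3.13 and 7.02, while the median level over windows was 44.4% in the control and 44.2% in the deletion library.

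**Figure D4:**
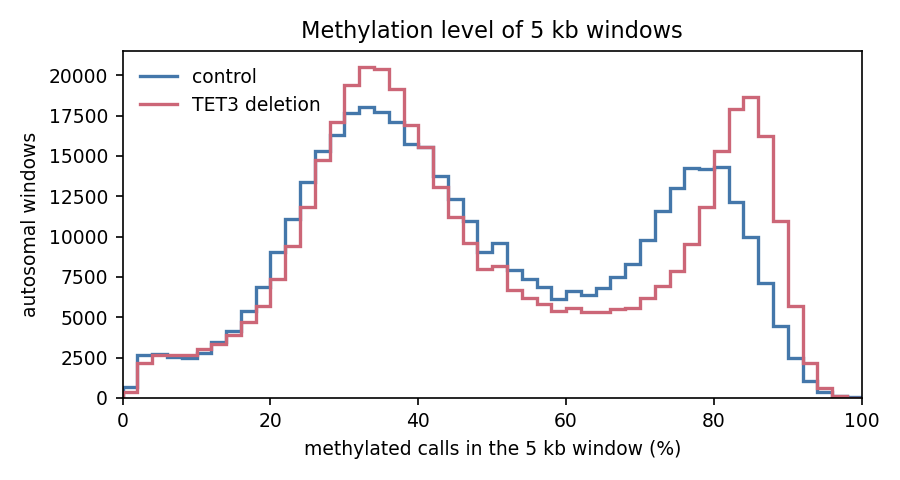
Number of autosomal 5 kb windows (y axis) by the percentage of methylated calls in the window (x axis) for the control and the deletion library. Windows at 80 to 100% make up 11.9% of windows in the control and 20.2% in the deletion library.

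Single 5 kb windows were then compared between the libraries over all chromosomes. Of 458282 windows, 55921 differed by at least 10 points at an adjusted p under 0.05 (Fisher's exact test, two-sided, Benjamini-Hochberg), 41354 of them higher and 14567 lower in the deletion library. When the genome-wide difference was taken off first, the split turned to 21429 higher and 28996 lower. That setting used a normal test in place of Fisher's exact test. Its minimum of 10 points was counted from the genome-wide difference, so the cuts on the plain difference were not symmetric. With Fisher's exact test and a minimum difference of 20 points the split was near even, with 4704 higher and 4426 lower. Autosomes held 40396 higher and 13389 lower windows, or 9.29% and 3.08% of those tested, and the X held 944 higher and 1174 lower. Of autosomal windows classed by level on the top strand, those of 60 to 80% were called higher most often, at 18.2%, and lower in 1.35%. Among autosomal windows of 20 to 40%, 7.89% were called higher and 4.32% lower. These calls used both strands, so the top strand served both to class and to call a window here.

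The size of these counts has to be read beside comparisons within a library, where no genotype differs. In 267637 windows with at least 50 calls on each strand, control and deletion calls of the top strand differed in 16.1% of windows, 12.6% higher and 3.44% lower. Top and bottom strands within the control differed in 14.7% of windows, 7.38% in one direction and 7.37% in the other, and within the deletion library in 14.3%. Set across strands in the same way, control calls of the top strand and deletion calls of the bottom strand differed in 20.7%, with 15.5% higher and 5.22% lower. Windows called higher on the top strand were also higher on the bottom strand in 72.1% of cases, against 63.5% of all windows, with a mean rise there of 4.90 points against 2.86 in all windows. Windows called lower on the top strand were lower on the bottom strand in 48.1%, against 36.4% of all windows, with a mean difference there of 0.440 points. With a chi-square test scaled to the spread between strands, 664 windows of 5 kb differed by at least 10 points, 646 higher and 18 lower, while the same test called 415 and 647 windows between the strands of the control and of the deletion library. Rises in the aggregate therefore stood above the spread between strands, and single 5 kb windows were not resolved. Strands of 1 library share its pool and preparation, so that spread leaves out differences between libraries that are not due to genotype. The excess of higher over lower windows is also not separate from the genome-wide rise. At 500 kb, 0 windows differed by at least 10 points at an adjusted p under 0.05. Without a minimum difference, 856 of 5133 windows of 500 kb were higher and 0 lower at that adjusted p by the scaled test, with 1440 higher and 1 lower at an unadjusted p under 0.05. Between the strands of 1 library this test, again without a minimum difference, called 3 and 4 windows. At 5 kb it called 691 higher and 34 lower between libraries against 436 and 692 between strands. The dispersion that scales the test came from these same strand comparisons, so their calls are not an independent measure of false calls. The comparison between libraries also drew on more calls per window than 1 strand gives. Dispersion rose with window size, to 21.6 at 500 kb, so the counts are not like for like. The scaled test and the larger windows were chosen after the data were seen.

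**Figure D5:**
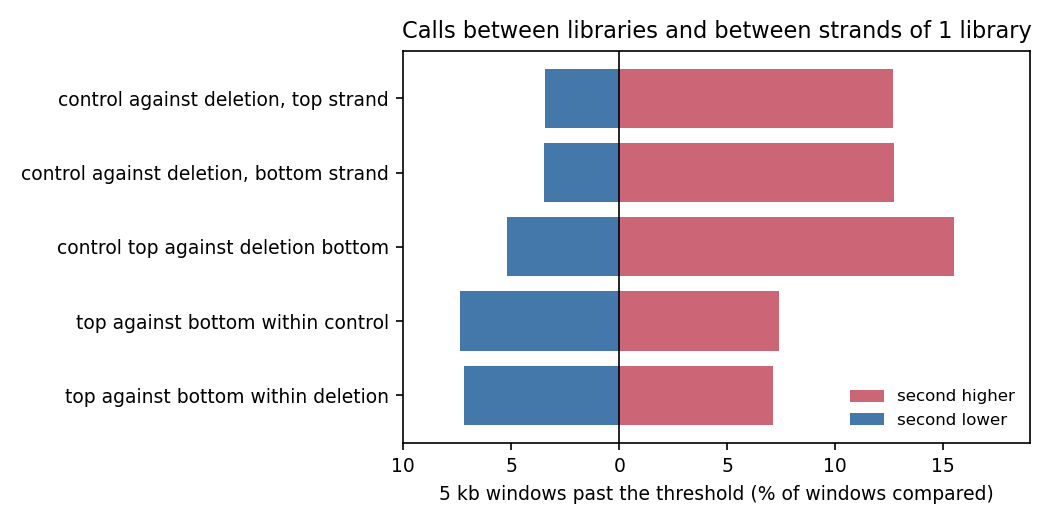
Share of 5 kb windows past the threshold (x axis, % of 267637 windows compared), to the right where the second member of the comparison was higher and to the left where it was lower, for the comparisons between libraries on each strand and across strands and those between strands of 1 library (y axis). Between libraries 12.6% were higher and 3.44% lower on the top strand and 15.5% and 5.22% across strands, while within the control 7.38% and 7.37% differed in the 2 directions.

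The windows with the largest changes in the same direction on both strands are given by NCBIM37 position, with 54 to 159 calls per library each; which genes they lie in is not analysed here. The largest rise was on chromosome 5 from 101565001 to 101570000, from 34.8% (23.5 to 47.6%) in the control to 79.1% (70.6 to 86.1%) in the deletion library (Fisher's exact test, adjusted p = 4.77e-07). The next rises were 43.7 points on chromosome 16 from 75950001 to 75955000, 42.8 points on chromosome 4 from 96790001 to 96795000, 42.6 points on chromosome 3 from 136485001 to 136490000 and 42.5 points on chromosome 17 from 7290001 to 7295000. The largest fall was on chromosome 1 from 97665001 to 97670000, from 68.4% (56.9 to 78.4%) to 15.1% (7.77 to 25.4%; Fisher's exact test, adjusted p = 4.64e-09). Methylation fell by 46.5 points on chromosome 8 from 104855001 to 104860000 and by 46.2 points on chromosome 15 from 20160001 to 20165000. It fell by 46.1 points on chromosome 11 from 42955001 to 42960000 and by 46.0 points on chromosome 10 from 28250001 to 28255000. Only 3 of these 10 windows, those on chromosomes 16, 4 and 17, had the 25 calls per strand that the strand-scaled test needs, and their adjusted p were 0.0534, 0.0942 and 0.0492.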

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

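The strand-scaled test, the 500 kb windows and the split by CpG spacing were chosen after the result was seen; the other settings in this part were planned. With no replicates, a level counted as moved when it changed by more than its counting interval, which is narrow at this depth, and a count when it changed by over 1.5 times. By that rule 64 alternative values of the class differences and window counts moved, 29 did not and 1 changed sign. Among X windows by level, the split of calls and single windows, 52 did not move, 12 moved and 1 changed sides. The Tet3 exon ratio stayed under 1 at 0.640 and 0.614 with other denominators (Fisher's exact test p = 0.0073 and 0.00411). Those settings kept the same 79 and 66 exon calls, so they do not test the exon counts themselves. The autosomal, X, Y, density and level differences kept their sign in every alternative fixed beforehand. In the split by CpG spacing, X differed by 1.51 points in patterns that occur at least 100 times, and the autosomal class of 1 to 5 CpGs by -0.287. Values that moved follow in percentage points, and except where the construction shows it, the cause was not tested.

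With at least 5 calls per position, X differed by -0.108 and Y by 3.49. The density classes from sparse to dense rose by 2.06, 3.97, 3.64, 1.07 and 0.548, and the level classes under 20%, 20 to 40%, 40 to 60% and 80 to 100% by 0.662, 1.99, 2.19 and 5.25. Without positions over 20 calls, the density classes rose by 1.73, 3.51, 3.40, 0.753 and 0.573 and the class under 20% by 1.04; this setting gave no mitochondrial value. With positions listed in both libraries, autosomes rose by 2.66, the 4 sparser density classes by 1.91, 3.74, 3.60 and 0.795, and the 5 level classes by 0.809, 1.83, 2.13, 5.42 and 5.10. With equal weight per position, autosomes rose by 2.32, X differed by -0.398 and mitochondrial DNA by -0.170, the density classes rose by 1.26, 3.02, 2.92, 1.48 and 0.797, and the level classes by 1.02, 1.49, 1.69, 4.94 and 4.72.

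Values on 1 strand leave out positions without an inferred strand, so the 2 strands need not average to the value over all positions. On the top strand alone, autosomes rose by 2.86, X differed by -0.191 and mitochondrial DNA by 0.123, and the 4 sparser density classes rose by 2.07, 3.68, 3.52 and 0.834. Classed on the bottom and measured on the top strand, the 3 lower level classes rose by 1.02, 1.75 and 2.05. On the bottom strand alone, autosomes rose by 2.85, X differed by -0.172, and the density classes rose by 2.01, 3.70, 3.48, 0.574 and 0.524. Autosomal CpGs in spacing patterns that occur once rose by 3.51, and those in patterns that occur at least 100 times by 1.52.

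X windows under 20% differed by -1.82 with positions listed in both libraries, and those of 80 to 100% by 2.62 with equal weight. On the top strand, X windows of 20 to 40%, 60 to 80% and 80 to 100% differed by -1.70, 2.24 and 2.60. Of the named windows, that on chromosome 17 differed by 65.1, that on chromosome 1 by -90.9 and that on chromosome 15 by -23.9 on the bottom strand, and that on chromosome 8 by -29.6 on the top and -61.9 on the bottom strand.

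Against 55921 called windows, a difference of 20 points left 9130 with 51.5% higher. Keeping 1 position per 100 bp left 9599 of 306496 windows tested, with 84.2% higher and fewer calls per window. Windows of 2 kb gave 99593 and of 10 kb 23964. These were 14.1% and 9.49% of the windows tested, against 12.2% at 5 kb, so the shares changed less than the counts. The strand-scaled test gave 664, and 500 kb windows with that test and no minimum difference gave 856. Without a minimum difference that test called 699 windows higher and 3 lower at 20 kb, where strands of 1 library gave 442 and 833. At 100 kb it called 343 higher and 1 lower, where strands gave 37 and 127. The strand counts are not an independent measure of false calls, since the scaling came from the same strand comparisons. The size of 500 kb was picked from these sizes after the counts were seen. Taking off the genome-wide difference turned the share of called windows that were higher from 74.0% to 42.5%. That setting also replaced Fisher's exact test with a normal test and counted the minimum difference from the genome-wide difference. At these depths a chi-square test divided by the simulated dispersion recovered 54% and 96.5% of simulated windows changed by 20 and 40 points when calls were independent. When calls were correlated it recovered 11.5% and 55%. The dispersion was known there and not estimated from strands, so the strand-scaled test itself was not checked. Promoters, gene bodies, feature classes and gene lists, with their alternatives, were not run. No paired analysis was possible because each genotype has 1 library.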

Other observations

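Except for the correlation across X clusters and the correlation across 500 kb regions, the tests in this part were chosen after the result was seen.

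Stretches of CpGs whose spacing recurs many times in the genome, as copies of a repeat family would, were on average more methylated than stretches whose spacing pattern occurs once. A pattern seen once does not show that the sequence has a single copy. Of 8403979 stretches of 6 CpGs spanning 40 to 400 bp, 210272 had a spacing pattern that occurred at least 100 times, against 0 after the gaps were shuffled. The X held 9.49% of the recurring stretches and 2.82% of all stretches. On autosomes, CpGs in patterns seen once went from 41.0% in the control to 44.5% in the deletion library, a rise of 3.51 points, and those in recurring patterns from 57.5% to 59.0%, a rise of 1.52 points. This contrast depended on CpG density: at 21 to 30 CpGs per 500 bp the rises were 1.64 and 1.47 points, and at over 30 the order turned, with 0.821 points in patterns seen once (5.30% to 6.12%) and 1.63 points in recurring patterns (58.9% to 60.6%). On the X, patterns seen once differed by -0.213 points and recurring patterns by 1.51 points. By density, recurring X sequence differed by 0.0337 points at 6 to 10 CpGs, 0.615 at 11 to 20 and 2.32 at over 30, against 2.24, 1.59 and 1.63 on autosomes. Which repeat families these are is not analysed here.

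CpG-dense clusters, runs of at least 200 bp with over 30 CpGs per 500 bp and at least 50 calls in each library, were mostly unmethylated. Of 15055 autosomal clusters, 84.6% lay under 20%, with a median of 1.48% in the control and 1.94% in the deletion library. Clusters of 20 to 80%, 2011 on the autosomes, had medians of 55.7% and 57.7%. Among 500 kb regions, the largest of the rises that passed the strand-scaled test were 8.29 points on chromosome 2 from 158500001 to 159000000, where methylation went from 48.2% to 56.5%, and 7.80 points on chromosome 4 from 138500001 to 139000000. These regions were singled out after their values were seen.

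A hypothesis was that the methylation level of a region accounts for how the difference varies between 500 kb regions. Across 4807 autosomal regions of 500 kb, which are not independent replicates, the level on the top strand and the difference on the bottom strand had Pearson's r of 0.165 and Spearman's rho of 0.148. An r over 0.3 had been set as bearing the hypothesis out and one under 0.1 as against it, so this value leaves it open. The mean difference was 1.67, 1.47, 1.79 and 2.70 points in 4 groups of regions from the least to the most methylated.

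The X did not rise with the autosomes, and its lowly methylated CpG clusters were lower in the deletion library. In 342 such clusters the median was 4.48% in the control and 2.49% in the deletion library, with a median difference of -1.49 points. Sets of lowly methylated autosomal clusters, 10000 in all, gave medians of 1.22 to 1.84%, 1.62 to 2.34% and differences of 0.118 to 0.795 points. These sets were matched on the number of listed positions per cluster only, and not on methylation level, calls or CpG density. Multi-copy sequence piled up at positions over 20 calls is argued against, as the difference was -1.63 points without them. That filter changed little, with a control median of 4.46% in 342 clusters, and kept multi-copy positions with fewer calls. X CpGs at over 30 per 500 bp differed by -1.59 points in spacing patterns seen once and by 2.32 in recurring ones. Another share of male zygotes is argued against too. It would have needed 54.6% more Y calls relative to autosomes where the ratio was 0.884, a gap wider than the 0.278 that the joint shortfall of X and Y calls allows. Another hypothesis, DNA of female somatic cells in both pools and more in the control, stays open. The inactive X of such cells is methylated at such clusters, and no step that removes such cells is given in the sources used here. X medians were raised in both libraries. Relative to autosomes, X calls should then have fallen and Y calls risen. X calls fell by 5.39%, the direction predicted, but Y calls fell by 11.6%, which goes against the hypothesis. A different share of female DNA alone would leave the joint value of X and Y calls unchanged. That value changed by -6.94%, beyond the lowest autosome at -3.18%. The cause of the joint fall was not tested, so coverage of the sex chromosomes decides neither way. If 1 source fed both libraries, cluster levels should have correlated at a rho over 0.5, and the rho of 0.214 was under the 0.3 set as excluding it, but a check added afterwards found a rho of only 0.0948 between the strands of the control and 0.380 between those of the deletion library, so the levels are too noisy for that test, and an effect of TET3 on the X was not tested.

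The rise was larger in highly methylated windows. Less complete bisulfite conversion is argued against: the class of 60 to 80% would have needed 18.1% of its unmethylated calls to stay unconverted, and mitochondrial DNA rose by 0.205 points. CpG density is argued against as well, since within each of the 5 density classes windows of 60 to 80% rose by more than those of 20 to 40%, by at least 1.75 points. More somatic DNA in the control could hide part of the rise in less methylated windows; X windows of 20 to 40% differed by -1.48 points where autosomal ones rose by 1.79, but without a somatic reference the size of that effect cannot be told apart from a smaller effect of TET3 there.

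The sizes of the differences in called 5 kb windows, and many of the windows called lower, may come from calls of the same read or its copies being counted as independent. Those called lower on the top strand had a mean difference of 0.440 points on the bottom strand, against -19.1 on the strand they were called on and 2.86 for all windows. Windows called higher shrank alike, from 17.5 to 4.90 points, so this is not particular to falls. Some true falls among them are not excluded, since the bottom-strand mean still lay under that of all windows.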
